A study of Mus musculus with 2 samples.

How the data were processed

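H3K9ac, acetylation of lysine 9 of histone H3, was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in hearts of mouse embryos at embryonic day 16.5. The series held 1 group of 2 samples, which the labels give as biological replicates of pooled embryos of mixed sex from the strain B6NCrl. The label of replicate 2 states 41 pooled embryos, and the number behind replicate 1 was not stated. The labels give a library size range of 300 to 500 bp for both.

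The authors deposited 4 peak lists on the mm10 build: 1 for each replicate, 1 pooled over both replicates and 1 of replicated peaks. The notes record the pooled list as derived from both alignments, so it is a single list with no spread between replicates. Besides its alignment, the replicate 1 list derives from 2 further source files and the replicate 2 list from 1, which is shared with replicate 1. These further files are not described, and the labels name a possible control experiment. The aligner, the peak caller, its thresholds and the control treatment are not given in the sources used here. The deposited columns were read in the usual order of the narrowPeak format. They give peak positions, a ratio read as fold over control by the convention of that format, and the deposited −log10 p and −log10 q of each peak. The fold and the −log10 values are the authors' own values per peak, and they served to describe, rank or filter peaks within a list. The signal tracks and alignments named in the notes were not used here. No numbers of reads are given in the files used, so the sequencing depth is unknown, and no interval that needs it is printed. Intervals on shares of peaks are Wilson 95% intervals and cover counting error only.

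Peaks on chromosomes 1 to 19 and X were kept, which left 72396 of 72407 peaks in replicate 1, 41114 of 41122 in replicate 2, 60573 of 60588 in the pooled list and 47200 of 47213 in the replicated list. No peak passed a chromosome end of the reference sequence GRCm38, the assembly that mm10 names. Genes came from GENCODE M21. The universe was 21701 protein-coding genes with a unique symbol, with 93012 annotated transcription start sites (TSSs). A gene was called marked when a peak overlapped the window of 1 kb on either side of any of its TSSs. Peaks were merged into domains at gaps of up to 1 kb, and a gene's TSS domain was the widest that reached such a window. Peaks more than 5 kb from every coding TSS were called distal and assigned to the gene with the nearest TSS. Coordinates are 1-based positions on mm10.

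Peak overlap required at least 1 bp. Overlaps and locations were compared with 100 shuffles of the peaks within chromosomes, assembly gaps excluded (bedtools 2.31.1), in one-sided permutation tests whose smallest p is 0.0099. The shuffles place peaks at random in the genome, a low bar for a promoter mark. A total of 20 gene lists, with 378 distinct genes, were fixed before the data were examined. They cover cardiac structures, cell types of the heart and tissues outside it, and 12 genes stand in more than 1 list. The atrial and ventricular lists share genes with the sarcomere, calcium and ion channel, and transcription factor lists, so their results are not independent. A single listed gene, Ahsp, had no match in the annotation. Shares of marked genes were compared with all other genes by two-sided Fisher's exact tests. Median domain widths were compared with 10000 random lists of marked genes matched on decile of CpG observed over expected within 500 bp of the gene's 5' end. Numbers of distal peaks were compared with 10000 random lists of genes, marked or not, matched on decile of territory. Territory is the stretch of genome nearest to a gene's TSSs. Both are two-sided permutation tests with a smallest p of 0.0002. Counts of 16 consensus motifs in distal peaks were set against flanks of equal width 5 kb away on either side, without those that overlap a pooled peak, and the ratio was ranked among up to 100 permutations of the same consensus with as many CpG in a one-sided test. The p-values of lists and motifs were adjusted by the Benjamini-Hochberg method over the 20 lists or 16 motifs. In the breadth test, lists with too few marked genes to test, such as the hepatocyte list, were left out of the adjustment. With 100 permutations, 4 motifs would have to exceed all their permutations for any to pass an adjusted p of 0.05. These tests treat genes or motifs as the units and describe this tissue sample, and genes are not independent replicates. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.

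Genes named in the text follow a rule fixed before the data were examined. It takes 20 landmark genes, for each list the 2 marked members with the widest TSS domain and the first unmarked member in list order, the 10 genes with the widest TSS domains, the genes at the 10 TSS peaks of highest fold, and the 10 genes with the most distal peaks. Other genes were named after their values were seen, and stand in the closing section.

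The tests were run on simulated data first. Over 21701 genes, the TSS test called 82% of planted lists marked at 95% against 60% and 5% of those marked at 80% against 60%. The breadth test called 70% of lists planted 2-fold wider and 30% planted 1.5-fold wider, over 13020 genes. The distal test called 10% of lists planted with 3-fold more peaks, so it can miss lists of that size. The motif test called 100% of 8 planted motifs when all were planted together, and 12.5% of the 8 others. They were planted 1.5-fold with at least 20 more sites per simulated segment. With so many planted at once, this does not give the power for fewer motifs.

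Alternatives fixed beforehand were a limit of −log10 q of at least 5, the 50% of peaks with the higher fold, each replicate list alone, the pooled list, other windows, merging gaps and distances, and other backgrounds. Chosen after the data were seen were the replicate 1 list limited to the length of the replicate 2 list, the replicated peaks that overlap both replicate lists, TSSs of basic transcripts only and up to 500 motif permutations. Sexes could not be compared, since embryos were pooled, and other stages or tissues were not analysed here.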

Results

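H3K9ac, a histone acetylation found at active promoters, was mapped by ChIP-seq in the mouse heart at embryonic day 16.5. The samples formed 1 group of 2 biological replicates, so the comparisons are those between the replicates and those between genes within the heart. The authors' list for replicate 1 held 72396 peaks covering 44.0 Mb of chromosomes 1 to 19 and X. The list for replicate 2 held 41114 peaks covering 28.1 Mb. Their list of replicated peaks held 47200 peaks covering 39.0 Mb, with a median width of 546 bp and a median fold over control of 4.55. Read depth is unknown. Fold values are the authors', one per peak.

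Peaks gathered at gene starts. For locations, the TSSs of all annotated genes were used, coding or not. Of the replicated peaks, 49.9% lay within 1 kb of such a TSS, 5.77 times the 8.65% of shuffled peaks (permutation p = 0.0099, the smallest that 100 shuffles can give). Introns held 29.1% of replicated peaks against 35.5% of shuffled ones, and sequence between genes held 15.2% against 48.7%. Peaks at TSSs were higher and wider, with a median fold of 9.57 and a median width of 953 bp, against 3.55 and 373 bp in introns. The peaks of highest fold stood at Actb (49.3) and Actg1 (47.2), which encode cytoplasmic actins, at Mat2a (47.7), which makes S-adenosylmethionine, and at the splicing factor genes Srsf4 (47.2) and Srsf6 (45.4). Atp5g3 (46.9), a subunit of ATP synthase, Ddx6 (45.4), Ube2l3 (43.7), Irf2bp2 (43.6) and Srf (44.7), a transcription factor of muscle and cytoskeletal genes, completed the 10 highest. Exons held 5.70% against 7.16%. The share at TSSs was 58.8% in replicate 2 and 38.8% in replicate 1. In replicate 1 alone the shares in introns (37.5% against 36.7% shuffled) and exons (6.56% against 6.32%) lay above the shuffled ones.

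Replicate 1 and replicate 2 marked largely the same genes. Of 21701 protein-coding genes, 14524 (66.9%) carried a peak at a TSS in replicate 1 and 13783 (63.5%) in replicate 2, a mean of 65.2% ± 2.41 (SD, n = 2). Both lists marked 13704 genes, 820 were marked in replicate 1 alone and 79 in replicate 2 alone. Endothelial Vwf (von Willebrand factor) and the pericyte gene Rgs5 were among the former, with folds of 2.56 and 2.98. Across genes marked in both, which are not independent replicates, Spearman's rho was 0.87 for the fold of the highest TSS peak and 0.88 for the width of the TSS domain. The replicated list marked 14175 genes (65.3%).

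Peak by peak, 91.5% of replicate 2 peaks (Wilson 95% interval 91.2 to 91.7) overlapped a replicate 1 peak, against 3.90% after shuffling. In the other direction 45.8% of replicate 1 peaks (45.5 to 46.2) overlapped replicate 2, against 2.23% (permutation p = 0.0099 for both). With an overlap of at least 50% of both peaks these shares were 59.6% and 33.9%, and with both lists limited to the same number of peaks by fold 81.8% and 69.0%. Replicate 1 peaks shared with replicate 2 had a median fold of 6.60, and 57.7% of them lay at coding TSSs. Those not shared had a median fold of 3.20, and 14.9% lay at coding TSSs. In the highest fold quartile of replicate 1, 98.9% of peaks were shared. The authors' replicated list held 47200 of the 60573 pooled peaks (77.9%). Of the pooled peaks 52.2% (51.8 to 52.6) overlapped both replicate lists, as did 66.7% of the replicated ones. A further 12940 replicated peaks overlapped replicate 1 alone, 1229 overlapped replicate 2 alone and 1540 overlapped neither.

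Genes of the heart muscle cell were marked throughout. All 25 sarcomere genes (Fisher's exact test with Benjamini-Hochberg adjustment over 20 lists, adjusted p = 1.87e-04), all 23 cardiac transcription factor genes (3.97e-04), all 13 ventricular genes (0.00962) and all 20 genes of fatty acid oxidation and muscle mitochondria (6.06e-04) carried a peak in the replicated list and in both replicate lists. Among them were Nkx2-5, Gata4, Tbx5, Tbx20, Hand2 and Mef2c, which regulate heart development, and Myh6, Myh7, Actc1, Myl2, Myl7, Tnnt2 and Ttn, which encode parts of the contractile apparatus. Of the genes of calcium handling and ion channels, 17 of 18 were marked (0.0141), with Pln, which encodes the calcium pump inhibitor phospholamban, and Slc8a1, the sodium-calcium exchanger, as the widest. Sln, which encodes sarcolipin, was not marked. Atrial genes were marked in 13 of 15 cases, a share of 86.7% that did not pass Fisher's exact test (adjusted p = 0.110). The exceptions were Sln and Nppa, the gene of atrial natriuretic peptide, which had no peak at its TSS in any list, while the neighbouring Nppb did, with a fold of 8.81. Nppa lies on chromosome 4 from 148000722 to 148002079, and the nearest replicated peak was 12784 bp away. A gene with no called peak is not shown to lack the mark.

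**Figure D1:**
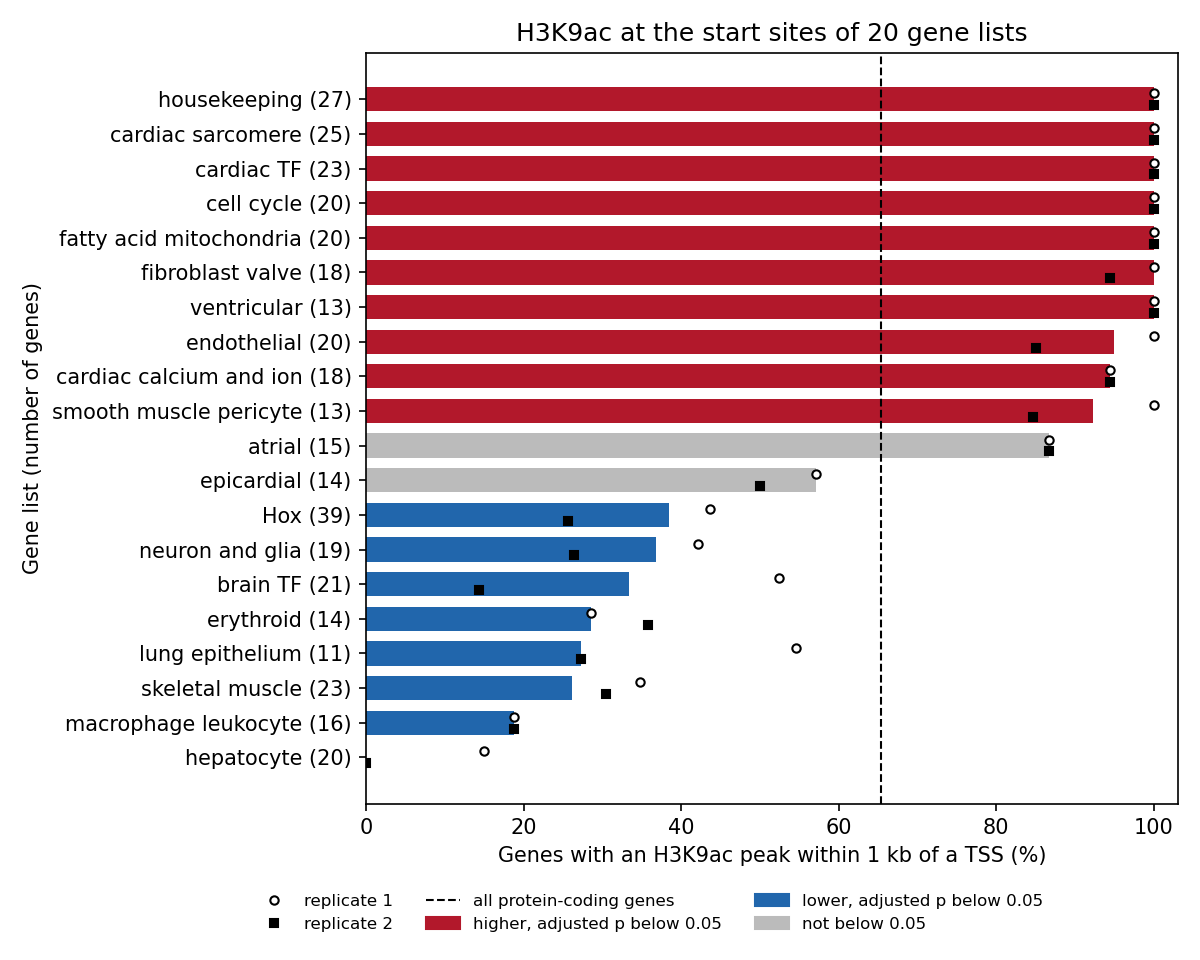
Percent of genes with an H3K9ac peak within 1 kb of a TSS (x axis) for 20 gene lists (y axis, number of genes in brackets). Bars give the replicated list, circles replicate 1, squares replicate 2, and the dashed line all protein-coding genes at 65.3%; hepatocyte genes stand at 0% in the replicated list and the sarcomere list stands at 100%.

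Lists of other cell types present in the heart varied. All 18 genes of fibroblasts and valve mesenchyme (Fisher's exact test, adjusted p = 0.00140), 19 of 20 endothelial genes (0.00669) and 12 of 13 smooth muscle and pericyte genes (0.0476) were marked, among them Sparc and Vcan of the extracellular matrix, Egfl7 and Fli1 of the endothelium, and Cspg4 and Pdgfrb of pericytes. All 27 housekeeping (1.59e-04) and all 20 cell cycle genes (6.06e-04), such as Mki67 and Rrm2, were marked. Epicardial genes were marked in 8 of 14 cases, which did not pass (0.578). Wt1 and Tbx18 were marked and Upk3b was not. Of macrophage and leukocyte genes 3 of 16 were marked (6.06e-04), Cd14 and Laptm5 among them, Laptm5 not in replicate 2, and Cd68 was not. Of erythroid genes 4 of 14 were marked (0.0116), with peaks at Tal1 and Epor and none at the globin genes Hba-a1 and Hbb-bt. The globin result is uncertain, because 25% of the 31-base words around the start of Hba-a1 and 56.4% of those around Hbb-bt occurred once in the genome.

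Lists of tissues outside the heart were marked less often than the other genes. None of 20 hepatocyte genes, Alb included, was marked in the replicated list (Fisher's exact test, adjusted p = 1.25e-08). Replicate 1 marked 3 of them and replicate 2 none. Of skeletal muscle genes 6 of 23 were marked (6.06e-04). Myod1, the myogenic regulator, was not, and the widest domain of that list belonged to Tnnt1, whose 14608 bp domain also covers the neighbouring cardiac gene Tnni3. In replicate 2 the domains of Tnnt1 (3246 bp) and Tnni3 (5056 bp) were separate. Mylpf, a fast muscle myosin light chain gene, had a peak of fold 25.1 near its start, with the summit of the domain outside the gene. Of lung epithelial genes 3 of 11 were marked (0.0244), Abca3 and Ager among them, and Sftpa1 was not. Of neuronal and glial genes 7 of 19 were marked (0.0174), with Phox2a and Elavl4 marked and Sox10 unmarked. Of brain transcription factor genes 7 of 21 were marked (0.00729), Dlx5, Lhx2 and Sox2 among them, and Foxg1 was not. Replicate 2 lacked peaks at Lhx2 and Sox2, the latter marked by a single peak of 186 bp, and marked 3 genes of the list. Hox genes, which pattern the body axis, were marked in 15 of 39 cases (0.00140), Hoxa2 and Hoxb2 with the widest domains of the replicated list, and Hoxa3 was unmarked. The Hoxa2 domain spanned 5986 bp in replicate 1 and 543 bp in replicate 2. The share of brain transcription factor genes was 52.4% in replicate 1 and 14.3% in replicate 2, the largest gap of any list. In all, 10 lists stood above and 8 below the other genes. Against random lists with matched promoter CpG, the erythroid (permutation test, adjusted p = 0.944), macrophage (0.733), lung (0.371) and cell cycle (0.733) lists no longer passed. Without replicate 1 the endothelial (0.0714), smooth muscle (0.160) and erythroid (0.0598) lists did not pass, and without replicate 2 the brain (0.186) and lung (0.522) lists did not.

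Cardiac genes were among those with the widest H3K9ac domains. The median TSS domain of all marked genes was 1876 bp. The widest was at Gata4, 22015 bp on chromosome 14 from 63234880 to 63256894 inside the gene, with 23368.5 bp ± 6086 over the replicates (SD, n = 2). Other cardiac genes among the widest 10 were Gata6 with 20953 bp (17530 ± 5733), the ventricular myosin heavy chain gene Myh7 with 20460 bp (20240 ± 24.0), Nkx2-5 with 19282 bp (15154.5 ± 5734) and Hand2 with 18279 bp (18708 ± 8631). The model gene Gm17428 ranked beside Myh7 because it shares that domain, and had a domain of 5879 bp in replicate 1 and none in replicate 2. Bahcc1 with 19538 bp, Nfib with 17543 bp, Cxxc5 with 16787 bp and Crip1 with 16386 bp completed the widest 10. In replicates 1 and 2 the domains spanned 19576 and 8529 bp at Bahcc1, 8725 and 13389 bp at Cxxc5, and 17702 and 2497 bp at Crip1, where the summit of the domain lay outside the gene. Other regulators with wide domains were Tbx5 (16321 bp) and Tbx20 (15639 bp), and among the sarcomere genes Tnni3 (14608 bp), Tnnt2 (12122 bp), Myh6 (11814 bp) and Actc1 (10932 bp). The Tnni3 domain spanned 15434 bp in replicate 1 and 5056 bp in replicate 2, and the Myh6 domain 11788 and 7143 bp. Nppb (2036 bp) lay close to the median of all marked genes. So did Myl7 (2266 bp), whose domain spanned 9898 bp in replicate 1 and 1669 bp in replicate 2.

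**Figure D2:**
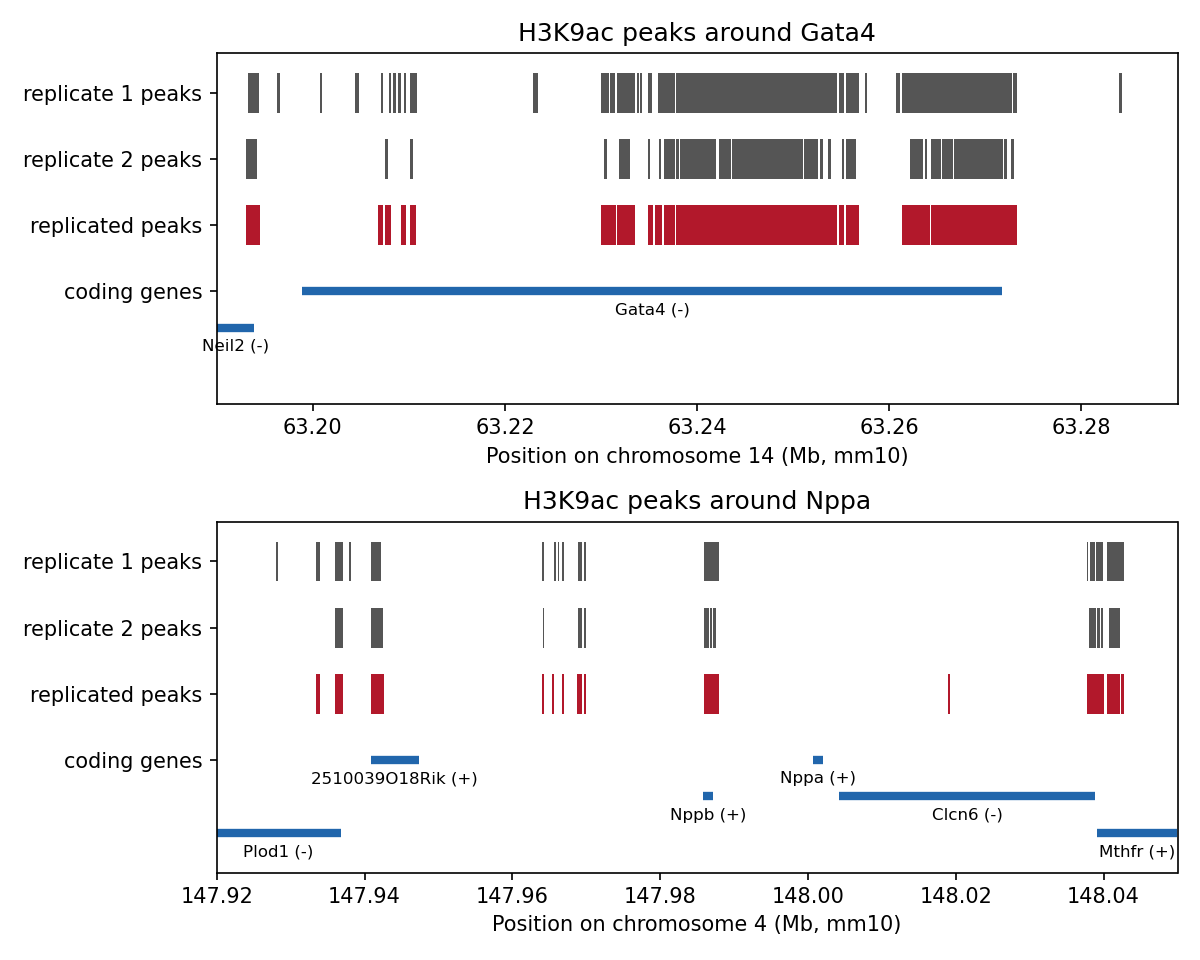
Peaks of replicate 1, replicate 2 and the replicated list (boxes, to scale) and coding genes (blue lines with strand) around Gata4 and Nppa, x axis in Mb of mm10. Replicated peaks form the Gata4 domain from 63234880 to 63256894, and the peak nearest to Nppa lies 12783 bp from the gene, in replicate 1.

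By list, the median domain was 7518 bp for the 13 ventricular genes, where random lists with matched CpG had a median of 1756 bp. It was 6856 bp for the 25 sarcomere genes (random 1568 bp), 6799 bp for the 23 cardiac transcription factors (1900 bp) and 5513 bp for the 17 marked genes of calcium handling and ion channels (1713 bp). Each had an adjusted p of 0.000543 by permutation against random lists, with an unadjusted p of 0.0002, the smallest that 10000 lists can give. Several ventricular genes, Myh7, Myl2 and Pln among them, also stand in 1 of the other lists just given, so the ventricular result is not independent of those. The housekeeping list was wide to a lesser degree, at 3357 bp (1862 bp, permutation test, adjusted p = 0.000543), led by Actb (8339 bp) and Rpl13a (8213 bp with the summit outside the gene, but 3835 and 3646 bp in replicates 1 and 2). Endothelial genes had a median of 3218 bp (0.000950; 2036 bp in replicate 2), cell cycle genes 3019.5 bp (0.00591), and fatty acid genes 2653.5 bp (0.0103), led by Ckm and Fabp3. Narrower than random lists were the marked genes of the brain transcription factor (286 bp, 0.000543), Hox (754 bp, 0.000543) and neuronal and glial lists (881 bp, 0.0280). The brain list had medians of 315 and 298 bp in replicates 1 and 2, the latter from 3 marked genes. Among replicated peaks that overlap both replicate lists, only 1 list passed as narrower. The atrial (2266 bp, permutation test, adjusted p = 0.152), fibroblast (2176 bp, 0.114), epicardial (1130.5 bp, 0.0785), smooth muscle (1858 bp, 0.469), erythroid (1694 bp, 0.871), macrophage (871 bp, 0.477), skeletal muscle (1913.5 bp, 0.647; 1224.5 and 1220 bp in replicates 1 and 2) and lung lists (1274 bp, 0.477; 648 bp in replicate 2) did not pass, and no hepatocyte gene could be tested. With a −log10 q of at least 5 the fibroblast list was wider (2467 bp, random 1555.5 bp, permutation test, adjusted p = 0.0190) and the lung list narrower (677 bp, random 1681 bp, 0.0429), while the neuronal and glial list did not pass (0.0606), nor did it in the 50% of peaks with the higher fold (0.0658). In replicate 1 alone the fibroblast (0.0175) and atrial lists (0.00909) were wider. In total 11 of the lists that could be tested passed, 8 wider and 3 narrower. Without replicate 1, the endothelial (permutation test, adjusted p = 0.0891), cell cycle (0.0557) and neuronal (0.113) lists did not pass; with no merging of peaks the housekeeping (0.118) and cell cycle (0.186) lists did not.

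**Figure D3:**
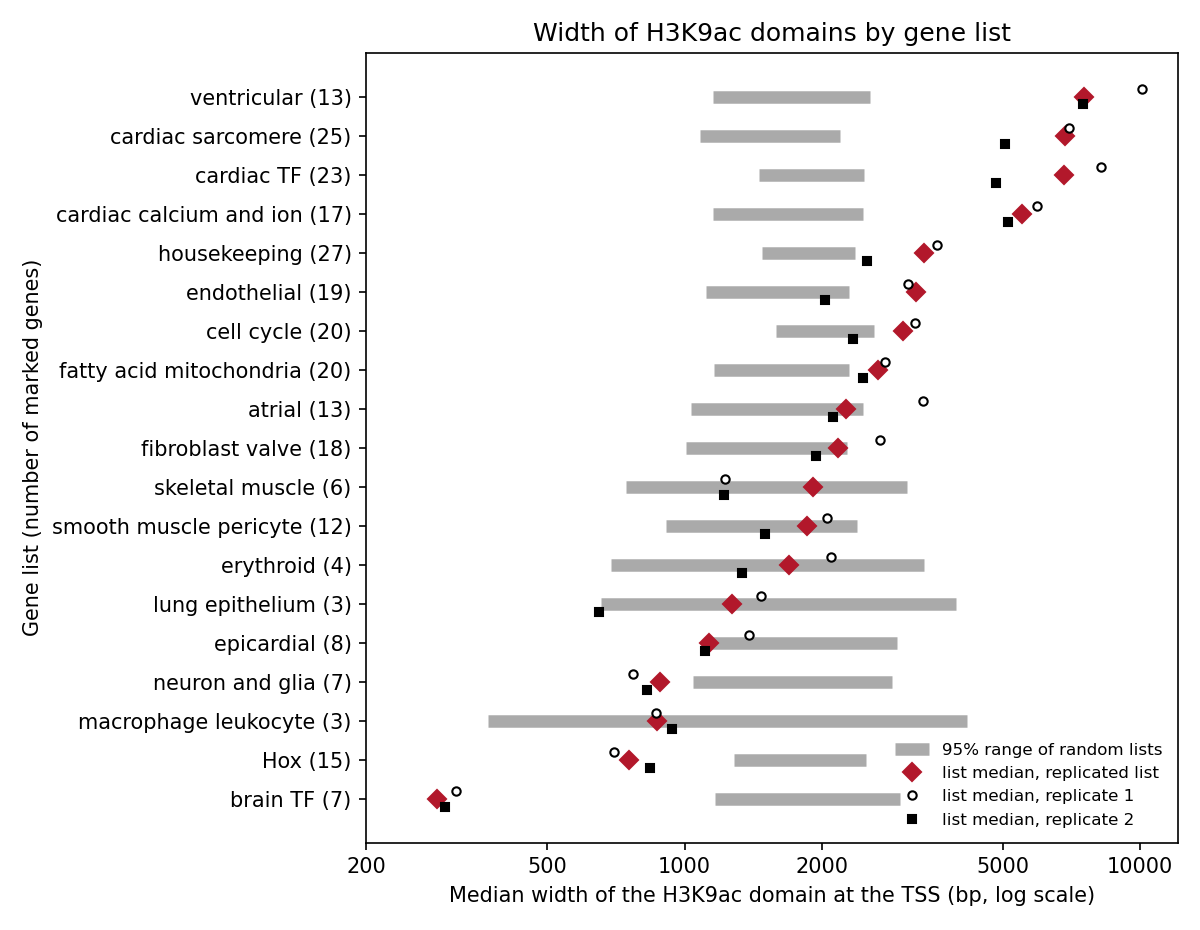
Median width of the TSS domain in bp (x axis, log scale) of the marked genes of each list (y axis, number of marked genes in brackets). Diamonds give the replicated list, circles and squares the replicates, and grey bars the 95% range of random lists with matched CpG; the ventricular list at 7518 bp and the sarcomere list at 6856 bp lie to the right of their ranges.

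Sarcomere and cardiac transcription factor genes had wide domains at average height. The median fold at the TSS was 15.9 for marked sarcomere genes and 16.5 for cardiac transcription factors, against 16.3 for all marked genes. Housekeeping genes had a median fold of 26.9. Lists with narrow domains had low folds as well, such as the brain transcription factor (3.84), Hox (4.92) and neuronal and glial lists (5.23). Gata4, with the widest domain, had a fold of 23.4, and Actb, with the highest fold, a domain of 8339 bp.

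**Figure D4:**
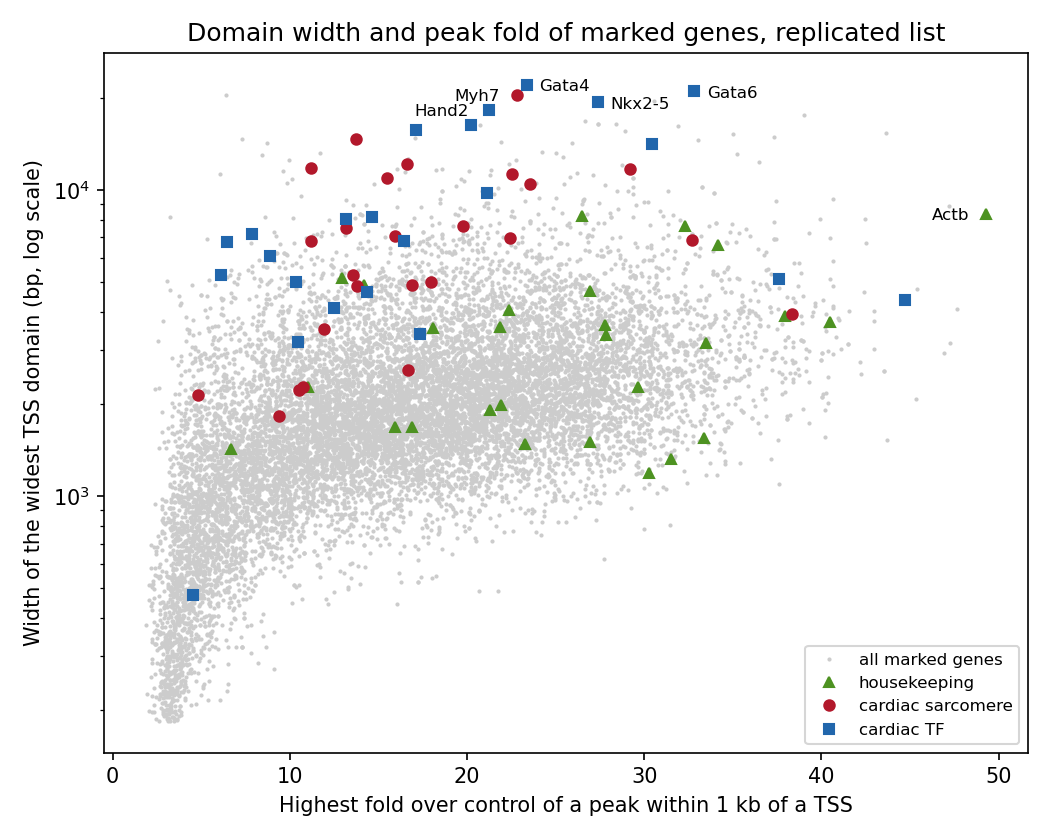
Width of the widest TSS domain (y axis, bp, log scale) against the highest fold of a TSS peak (x axis) in the replicated list, 1 point per marked gene. Grey points are all 14175 marked genes, and coloured points are the housekeeping, sarcomere and cardiac transcription factor (TF) lists, whose median folds were 26.9, 15.9 and 16.5.

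Away from coding TSSs, peaks clustered around cardiac regulators. Start sites of non-coding genes were not left out, so distal peaks include some at the starts of such genes. Distal peaks made up 38.7% of the replicated list (18268 peaks, median fold 3.69). They were counted unmerged, so a broad region made of several peaks counts several times. Parts of a wide TSS domain that lie more than 5 kb from every coding TSS count too. The numbers of distal peaks are thus not independent of domain width. Random lists were drawn from all genes, of which 65.3% were marked, while all 23 cardiac transcription factor and all 25 sarcomere genes were marked. The test thus does not separate a trait of these lists from a difference between marked and unmarked genes. The 23 cardiac transcription factor genes had 223 distal peaks in their territories, where random lists of matched territory had a median of 38 (permutation test, adjusted p = 0.0040). Of the genes of this list that the naming rule takes, Gata6 had 30, Gata4 17, Tbx5 16 and Nkx2-5 12. The highest number in the list, 38, belonged to a gene outside that rule. The genes of calcium handling and ion channels had 123 (random 25, permutation test, adjusted p = 0.0140) and the sarcomere genes 75 (random 17, 0.0493). The genes with the most distal peaks were Zmiz1 (71), a transcriptional coregulator, Gse1 (69), Casz1 (65), a zinc finger regulator of heart development, Zfp36l1 (50), Lrrfip1 (47), Rbm20 (47), a splicing factor of titin, Sipa1l2 (44), Ahdc1 (41), Msi2 (41) and Nfib (40). In replicates 1 and 2 the totals were 371 and 162 for the transcription factor list, 244 and 86 for the calcium and ion channel list, and 136 and 58 for the sarcomere list. Single genes differed too, as in Zmiz1, with 115 in replicate 1 and 40 in replicate 2. None of the other 17 lists passed. The nearest were the ventricular list with 71 peaks (random 16) and the housekeeping list with 37 (random 9), both at an adjusted p of 0.0696 by permutation. The ventricular list passed with a −log10 q of at least 5 (0.00533), in the 50% of peaks with the higher fold (0.0133) and without matching on territory (0.0180). Fatty acid genes had 40 distal peaks (0.151), endothelial genes 65 (0.176), atrial genes 47 (0.237), smooth muscle genes 26 (0.250), fibroblast genes 37 (0.713), epicardial genes 10 (0.713), cell cycle genes 12 (0.687) and macrophage genes 13 (0.687). Hepatocyte genes had 2 (0.151), brain transcription factors 14 (0.339), Hox genes 2 (0.497), erythroid genes 1 (0.519), skeletal muscle genes 8 (0.526), lung genes 9 (0.687), and neuronal and glial genes 14 (0.713). The sarcomere list did not pass with peaks more than 10 kb from a coding TSS (permutation test, adjusted p = 0.127).

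Sites of the MEF2 factors, which regulate muscle genes, were denser in distal peaks. The consensus CTAWWWWTAG reads the same on both strands, so each site was counted once per strand. Its counts were 0.0753 per kb in distal peaks and 0.0326 per kb in flanks. The ratio, which this counting leaves unchanged, was 2.31 (log2 1.21, SE 0.13 from leaving out chromosomes in turn), above all 100 permutations of the consensus. The TEAD consensus ACATTCC had a ratio of 1.23 (log2 0.30, SE 0.05), also above all its permutations. None of the 16 motifs passed the adjusted threshold in this permutation test, in which 3 had an unadjusted p under 0.05: MEF2 and TEAD (adjusted p = 0.0792 for both) and FOXA (0.211), whose ratio was 0.973. With up to 500 permutations, a setting chosen after the data were seen, MEF2 (adjusted p = 0.0319) and TEAD (0.0381) passed. In that setting MEF2 passed in each replicate list alone (0.0319 in both), and TEAD passed in replicate 1 (0.0381) and not in replicate 2 (0.0762). The GATA consensus was less dense in peaks than in flanks (ratio 0.704) and did not stand out from its permutations (adjusted p = 0.668). The ratios of the others were 2.31 for ETS, 1.06 for AP1 and 0.904 for NKX2 (adjusted p = 0.218 for each by permutation). With the same p, counts of the E-box CAGCTG were 1.78 per kb in peaks and 1.05 in flanks, and those of HNF4 0.0518 and 0.0431. The E-box too reads the same on both strands, so each of its sites was counted once per strand. Ratios were 0.625 for HNF1 (0.246), 0.881 for SOX (0.380) and 0.865 for the SRF site (0.461). They were 1.01 for TBX and 0.722 for the POU octamer (0.500 for both), 0.925 for REST (0.760) and 1.16 for CTCF (0.980). Permuted consensuses had unequal ratios too, so a ratio alone does not show enrichment. The log2 ratio minus the median of the permutations was 2.08 for MEF2, 0.31 for ETS, 0.22 for NKX2 and −0.70 for CTCF.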

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

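The test of weak peaks in this part was chosen after the result it bears on was seen, and the test of broken regions before. Data outside the comparisons held signal in 4 places. There were 5 replicated peaks on chromosome Y and 8 on unplaced contigs. A further 1494 replicated peaks lay at the TSS of a long non-coding RNA with no coding TSS within 1 kb. Of the pooled peaks, 5465 overlapped neither replicate list.

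The lists of the 2 replicates differed in length, with 1.76 times as many peaks in replicate 1. Breaking of the same regions into more pieces is argued against: after merging at gaps of up to 1 kb, replicate 1 still had 1.73 times as many regions (44841 against 25849). A larger number of weak peaks near the calling threshold stays open. Of the peaks of replicate 1, 98.9% of the highest fold quartile were shared with replicate 2 but 45.8% of the whole list, a difference of 53.1 percentage points, yet with a −log10 q of at least 5 replicate 1 still had 1.49 times as many peaks (30286 against 20387), of which 60.9% were shared against 98.5% in replicate 2. Read depth, enrichment and the additional source file behind the replicate 1 list stay open, since none of them is given in the files used here, and no biological explanation was tested.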

How the results depend on the processing

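All values above rest on 1 group of 2 samples of unknown depth, and no reads were counted again, so what depth limits could not be measured. No paired analysis was possible because the series has a single group. The enrichment at TSSs and the overlap of the replicates passed their permutation tests in every alternative run, the share at TSSs lying between 38.8% (without replicate 2) and 75.4% (the 50% of peaks with the higher fold), and 58.8% without replicate 1. No gene list that passed changed direction. Lists that did not pass changed direction in 12 comparisons by breadth and 14 by distal peaks, among them the erythroid and skeletal muscle lists by breadth and the fibroblast, smooth muscle, cell cycle and lung lists by distal peaks, in no case with a pass in the alternative. The shares in introns and exons turned from below to above the shuffled ones in replicate 1 alone. The share of pooled peaks that overlap both replicate lists was 52.2%, but 41.6% when each list had to cover at least 50% of the pooled peak and 67.1% with a −log10 q of at least 5. The number of lists called at the TSS was 18, between 14 (matched CpG) and 18 in the alternatives, and 15 to 16 without a replicate. The number called by breadth was 11, between 8 (without replicate 1) and 13 (without replicate 2, and with the pooled list). The number called by distal peaks was 3, and 2 beyond 10 kb, 4 with a −log10 q of at least 5 or the higher-fold 50%, 6 without matching on territory and 5 with the replicate 1 list limited to as many peaks as replicate 2. The ventricular list was the one added in both settings with 4. Without matching on territory, the ventricular, endothelial and, with fewer peaks, Hox lists were added. The last setting, chosen after the data were seen, added the ventricular and housekeeping lists. No motif passed with 100 permutations in any alternative. With 500 permutations, also chosen afterwards, 2 passed, and 1 to 2 without a replicate; more permutations allow smaller p-values by construction. Otherwise the cause was not tested. Among 604 values of gene lists under alternatives, 33 lost and 16 gained their call; the smooth muscle list lost its TSS call in 7 settings. Other losses at the TSS were the brain list with the pooled list (Fisher's exact test, adjusted p = 0.382), and the neuronal (0.238) and lung (0.0635) lists with a window of 2.5 kb, the lung list in the replicate 1 list of limited length (0.0761), and the endothelial list among peaks in both replicate lists (0.0674). By breadth, the cell cycle list lost its call with a merging gap of 3 kb (0.0503), the Hox list in the replicate 1 list of limited length (0.0909) and among peaks in both replicate lists (0.105), and the endothelial list in the latter (0.105) and in the higher-fold 50% (0.0892). The fibroblast list gained a call by breadth with the pooled list (0.0141), a merging gap of 3 kb (0.0277) and peaks in both lists (0.0230), and the atrial list with the pooled list (0.0304) and no merging (0.00522). Of 765 widths of named genes under alternatives, 249 moved by more than the SD of the replicates, 207 to lower and 42 to higher values.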

Other observations

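The tests of the distance to the nearest peak and of the other atrial genes in this part were chosen after the results they bear on were seen, and the others before. The genes in the next paragraph were chosen after their values were seen.

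Wide domains also lay at long non-coding RNA genes with no coding TSS within 1 kb. The imprinted gene H19 on chromosome 7 had a domain of 9916 bp (142570725 to 142580640) with a highest fold of 12.6, Malat1 on chromosome 19 one of 9791 bp with a fold of 25.7, and Airn, the antisense transcript of the imprinted Igf2r region, one of 8145 bp with a fold of 18.6. B230312C02Rik, 50137 bp from Gata5, had a domain of 9556 bp with a fold of 27.0, and Gm15969, 5895 bp from Casz1, one of 7721 bp. CpG content around the gene's annotated 5' end went with marking. A peak at any TSS of a gene counted as marking, so CpG content and peak can belong to different start sites. In the lowest CpG decile 6.45% of genes were marked, in the highest 98.0%. In the lowest 2 deciles, 11.5% of all genes were marked, and 10 of 10 genes of the sarcomere, calcium and transcription factor lists, Gata4, Myh6, Myh7, Myl2, Tnnc1 and Tnnt2 among them. In the top 4 deciles, 238 of 8680 genes (2.74%) were unmarked in both replicates. Of the 12 protocadherin alpha genes, counted whatever their CpG decile, 11 were unmarked in both. Whether the sequence at their starts is unique was not checked.

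Nppa and Sln had no peak at the TSS, in a tissue where the other genes of the atrial list were marked. Reads shared with repeated sequence are argued against, since 100% of the 31-base words within 1 kb of either gene's start occurred once on chromosomes 1 to 19 and X. A signal displaced from the annotated start is argued against too, as the nearest peak of any list was 12783 bp from Nppa and 20046 bp from Sln. A low share of atrial cells stays open, since the marking of 13 of 13 other atrial genes excludes nothing where several of them, Tbx5 and Nr2f2 included, are active in other heart cells. A high signal in the control, a difference of the strain from the reference and a true lack of the mark stay open, and no biological explanation was tested.

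The wide domains at genes of the sarcomere, of calcium handling and ion channels, and of cardiac transcription factors were weighed against 3 technical explanations. Peak height is argued against, since in random lists matched on TSS fold each of the 3 medians was at least 2.01 times the upper bound of the 95% range. Domains shared with a neighbouring coding gene are argued against by the same ratio, at least 2.09 when genes with such domains were left out, and gene length by a ratio of at least 2.06 in lists matched on it. The number of annotated TSSs per gene was not matched and stays open, since the widest domain is taken over all TSSs of a gene. With no merging of peaks, the medians were 2742 bp, 3108 bp and 3394 bp against 1193 bp, 1305 bp and 1446 bp in random lists. A candidate explanation is that wide H3K9ac marks genes of cell identity in the heart muscle cell. It is a hypothesis, and with 1 tissue in the series it was not tested. The housekeeping, endothelial, cell cycle and fatty acid lists were wider than random lists as well, to a lesser degree.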
